A study of Homo sapiens with 4 samples.

How the data were processed

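Leukocytes were isolated from human breast milk by centrifugation and magnetic selection for CD45, and libraries were made with the 10x Genomics 3' v3.1 chemistry and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The 4 libraries fall into a transmitter and a non-transmitter group of 2 each, and no batch, date or donor number is given for them in the labels used here. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors made with Cell Ranger 7.2.0 on GRCh38, per the file headers and the submitters' processing notes, with no normalization. The feature list holds 36788 entries, of which 187 lack a human gene identifier. The lowest count in a barcode was 500 UMIs, so a minimum had been applied before deposition. Total counts and medians per library open the results. A count of 0 was read as at most 3 counts, and shares of cells carry exact Clopper-Pearson 95% intervals. Whether the counting used strand is not stated in the labels used here.

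Barcodes were kept with at least 500 UMIs, at least 300 detected genes and at most 20% of UMIs from mitochondrially encoded genes. This removed 9.71%, 15.0%, 3.96% and 1.69% of the barcodes in the order transmitter 1, transmitter 2, non-transmitter 1, non-transmitter 2, 993 of 12461 in all. Scrublet, run per library in scanpy 1.11.5, called 23 of 11468 barcodes (0.201%) doublets. Its threshold thus marked almost none, and an alternative removed the highest scores instead. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0, seed 1, without integration across libraries. Cells in T cell clusters were clustered again. A cluster was named for the class with at least 3 listed markers detected in at least 10% of its cells at 1.5-fold over the other cells and with a mean log2 fold of at least 0.5. Otherwise it stayed unnamed, as did clusters whose median UMIs were under 0.3333 of their library's with no listed marker among the top 10 genes. CD8 T cells were also taken by a gate: a UMI of CD3D, CD3E or CD3G, a UMI of CD8A or CD8B, and none of CD4. Python 3.11.15 ran with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

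Libraries, not cells, were the replicates. Shares of cells were compared by a two-sided exact permutation test of library values, and cell numbers per class by edgeR's quasi-likelihood test with total retained cells as offset. For expression, raw counts were summed per library and class in each class with at least 20 cells in every library. The CD8 class by cluster, with 3 cells in non-transmitter 1, was kept as the comparison the title names, with the gate beside it. Sums were tested in R 4.3.3 with edgeR 4.0.16 (TMM, filterByExpr, robust glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment at 0.05. Levels are given as UMIs scaled to a common library size (CPM). Folds against a group at 0 are bounds against 3 counts over the group, and with 1 to 3 counts the ratio is given with its exact interval.

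The 16 gene lists were tissue residence, recirculation, cytotoxic effector, T cell activation and checkpoint, interferon-stimulated genes, antigen processing class I, antigen presentation class II, homing receptors, inflammatory cytokines and chemokines, lipid handling, immediate early and heat shock, proliferation, oxidative phosphorylation, milk-secreting epithelium, neutrophil, and erythrocyte and platelet. They were tested with limma 3.58.1 camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The camera test compares a list with the other genes, and fry asks whether its own genes move one way. Residence markers were read per cell after thinning each cell to 2000 UMIs, leaving out cells with fewer. Of the markers set beforehand, 1 is not reported here. The groups, filters, tests, lists and the naming rule were set before the data were examined.

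Named genes are members of the lists, plus, per class, the 10 largest rises and falls (5 in classes other than CD8 T cells) among genes at adjusted p under 0.05 without overlap between groups and with a mean log2 CPM of at least 4. Where fewer than 5 such genes passed, the 10 genes of lowest p were given as values. Left out of naming were receptor and immunoglobulin segments, genes that reveal sex, mitochondrially encoded genes, clone-style names and genes with common presence or mapping polymorphisms. Genes outside the rule that are named because a count was small were chosen after their values were seen. Gene positions come from GENCODE 29 (58780 genes) on the same genome build.

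Alternatives were other cell filters (all deposited barcodes, or at least 1000 UMIs and at most 10% mitochondrial), doublets kept, Leiden resolution 0.5 and 2.0, libraries centred, the gate, DESeq2 size factors, DESeq2 1.42.0, no low-count filter or at least 10 counts in every library of a group, milk genes removed, equal cell numbers, a block by replicate number, each library left out, no thinning and thinning to 4000 UMIs. Others were added after the data were seen and are named as such in the closing section. The edgeR test was tried on simulated data at the class's own dispersion, for CD8 T cells by cluster and by gate, T cells, macrophages and neutrophils. In each, 200 changed genes were drawn from those with a mean log2 CPM of at least 4. No fitted model used batch, since none is given.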

Results

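Single-cell RNA profiles of white blood cells from human breast milk were compared between a transmitter and a non-transmitter group. The series title concerns passage of human cytomegalovirus (HCMV) through breast milk and protection by tissue-resident CD8 T cells. Each group had 2 libraries, and the labels do not say whether these come from separate mothers. Cells had been selected for CD45, a surface protein of white blood cells, so the selection sets in part which cells appear. The libraries held 4303 and 3072 barcodes in the transmitter group and 1287 and 3799 in the non-transmitter group. Their total counts were 45119168, 38055885, 6751086 and 46268999 unique molecular identifiers (UMIs). After filtering, 3881, 2609, 1235 and 3720 cells were retained, in the order transmitter 1, transmitter 2, non-transmitter 1, non-transmitter 2, which all lists of 4 values follow. Median UMIs per retained cell were 6818, 9745, 1452 and 9236.5, so non-transmitter 1 was the shallowest library. The p-values below measure only the spread between these libraries, and intervals and limits from counts of 0 cover counting error only. The smallest p that a two-sided exact permutation of 2 against 2 libraries allows is 0.333, so no share or ratio could pass 0.05.

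The first question was which cells the milk held in each group. T cells, the lymphocytes that recognise antigen through a rearranged receptor, made up 11.2% ± 3.83 (SD, n = 2) of retained cells in the transmitter group and 32.1% ± 1.13 (n = 2) in the non-transmitter group. Macrophages, the phagocytes that dominate milk, made up 18.6% ± 10.5 and 36.4% ± 13.7. Natural killer (NK) cells, lymphocytes that kill infected cells without that receptor, made up 0.787% ± 0.785 against 0.0674% ± 0.0192, from 9, 35, 1 and 2 cells. For these 3 classes the libraries of the groups did not overlap (p = 0.333 each, two-sided exact permutation, the smallest possible). T cells stayed apart under every alternative for filters, doublets and clustering, with differences of -20.4 to -23.6 points. Macrophages overlapped under each of these except removal of the highest doublet scores, and their difference of -17.8 points was -1.19 at Leiden resolution 2.0, -3.06 with stricter filters and -6.50 with doublets kept. It was -10.3 points without transmitter 1, -8.05 without non-transmitter 1 and -27.5 without non-transmitter 2. By library, macrophages made up 11.2%, 26.0%, 46.1% and 26.7%. Monocytes and macrophages together made up 46.7%, 30.3%, 47.0% and 46.9%, so transmitter 1 lay close to both non-transmitter libraries there. The pooled difference of -8.43 points was -0.247 without transmitter 2. The macrophage difference thus depends on the split from monocytes. NK cells overlapped with stricter filters and at Leiden resolution 2.0, and their difference of 0.719 points was 1.27 without transmitter 1 and 0.165 without transmitter 2. Subclusters led by myeloid genes held 27, 8, 127 and 188 of the T cells. Without them T cells made up 7.81%, 13.6%, 21.0% and 27.8% of the libraries, a difference of -13.7 points and still without overlap. Regulatory T cells, which restrain immune responses, were 13.6% ± 5.20 of T cells in the transmitter group and 5.20% ± 0.753 in the non-transmitter group, again without overlap (exact permutation p = 0.333), here and under every such alternative. Their difference of 8.40 points was 4.72 without transmitter 1. Regulatory T cells numbered 57, 36, 18 and 70. Relative to all retained cells their log2 ratio was -0.232 (SE 1.19, edgeR), opposite in sign. The higher share thus holds among T cells only, where the transmitter group had the lower T cell share, and was not seen among retained cells.

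CD8 T cells, which kill infected cells, were 7.00% ± 2.10 of T cells in the transmitter group and 6.61% ± 8.25 in the non-transmitter group when taken by cluster (n = 2 each, exact permutation p = 1). The 28, 20, 3 and 152 CD8 cells found this way left non-transmitter 1 with 3 cells. Without transmitter 1 the difference in CD8 share turned to -1.1 points, and without non-transmitter 1 to -5.44 points. It was 0.389 points in the main setting, 8.23 at Leiden resolution 0.5, 4.3 with libraries centred and -0.492 without myeloid-led subclusters. A gate on CD3 and CD8 genes without CD4 counts placed 66, 87, 69 and 233 T cells in the class, or 22.0% ± 2.80 against 18.5% ± 0.843 of T cells (exact permutation p = 0.333). This difference of 3.51 points turned to -3.38 with stricter filters and -1.02 without myeloid-led subclusters, and it was 5.5 without transmitter 1 and 1.53 without transmitter 2. The ratio of CD8 to CD4 T cells by cluster was 2.00, 0.667, 0.375 and 0.348 (exact permutation p = 0.333). With CD8 cells by gate over CD4 cells by cluster it was 4.71, 2.90, 8.63 and 0.533 (exact permutation p = 1). No gate was set for CD4 cells, and the divisors were 14, 30, 8 and 437 cells. CD4 T cells, the helper class, were 6.25% ± 2.84 against 18.9% ± 23.8 of T cells, and the difference turned to 4.18 points without non-transmitter 2. Gamma-delta T cells, with a less variable receptor, were 14.4% ± 10.9 against 9.36% ± 2.97, and the difference turned to -2.69 points without transmitter 2. This class joins a subcluster led by ME1, SLC4A10 and NCR3 (16, 38, 1 and 132 cells) with one led by GNG4, SOX4 and RASSF8 (6, 42, 27 and 8). Each was named on 3 detected markers, the least the rule allows, so the name is tentative. The libraries thus compare different subsets in this class. Unassigned T cells were 58.8% ± 6.41 against 59.9% ± 35.8 of T cells, and the difference turned to 3.41 points without transmitter 2, 24.2 without non-transmitter 1 and 6.29 without myeloid-led subclusters.

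Among the other classes, monocytes were 19.9% ± 22.1 against 10.6% ± 13.7 of retained cells, and dendritic cells, which present antigen to T cells, were 9.57% ± 7.56 against 3.49% ± 1.61. The monocyte difference turned to -6.27 points without transmitter 1, -0.355 without non-transmitter 1 and -0.818 with doublets kept. The dendritic cell difference of 6.08 points was 11.4 without transmitter 1 and 0.74 without transmitter 2. Neutrophils were 2.42% ± 2.07 against 4.46% ± 2.29, and B cells 0.444% ± 0.356 against 0.606% ± 0.0554 (n = 2 each). The neutrophil difference of -2.03 points was -3.5 without transmitter 1, -0.564 without transmitter 2, -3.65 without non-transmitter 1 and -0.41 without non-transmitter 2. It was -5.41 with doublets kept and -3.12 with libraries centred, without overlap in either. That of B cells turned to 0.0897 points without transmitter 2. Milk-secreting epithelial cells, which CD45 selection should deplete, were 4.34% ± 2.60 against 2.82% ± 2.31. That difference turned to -0.319 points without transmitter 2 and to -0.118 without non-transmitter 2. Clusters that received no name held 32.8%, 24.0%, 11.3% and 7.5% of the libraries. The largest of these had a median of 704 UMIs and 1041, 468, 3 and 83 cells, so shallow barcodes enter the total of which shares of retained cells are taken. By mean marker fold its closest class was neutrophil, as for another unnamed cluster of 186, 126, 36 and 196 cells. Neither met the naming rule. The neutrophil shares thus cover the named cluster only, and counting these cells as neutrophils would reverse the direction of their difference. In edgeR's quasi-likelihood test of cell numbers, 0 of 15 classes passed after Benjamini-Hochberg adjustment (lowest adjusted p = 0.383), and 1 had an unadjusted p under 0.05. This was the plasmacytoid dendritic cell (log2 ratio 4.99, SE 1.94, unadjusted p = 0.0299). It made up 0.387%, 7.17%, 0.243% and 0.0269% of the libraries, so most of its cells came from transmitter 2. Leaving out 1 library at a time gave lowest adjusted p between 0.158 and 0.719. No other tool was run on cell numbers.

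Within a class, the libraries drew on different clusters, and several of these came mostly from a single library rather than from a group. The macrophage cluster led by FABP4, a fatty-acid carrier, and the chemokine CCL18 held 320, 441, 24 and 7 cells. The one led by HS3ST2, GPNMB and the galectin LGALS3 held 63, 172, 60 and 870. A shallow macrophage cluster led by APOE and CTSD held 26, 46, 422 and 35. Among monocytes, the cluster led by the interferon-induced chemokines CXCL10 and CCL8 held 16, 8, 4 and 543 cells. The cluster led by CXCL5, CCL20 and IL1B, which recruit and alert other white blood cells, held 608, 8, 0 and 10. T cells in a cluster led by TSHZ2, LTB and CCR6 numbered 66, 126, 45 and 704, and those led by the chemokines XCL1 and XCL2 numbered 123, 151, 178 and 15. The milk-secreting epithelial cluster led by MGP, SERPINA3 and CLDN4 held 53, 103, 32 and 5 cells, and the one led by LALBA and CSN2 held 44, 58, 23 and 39.

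**Figure D1:**
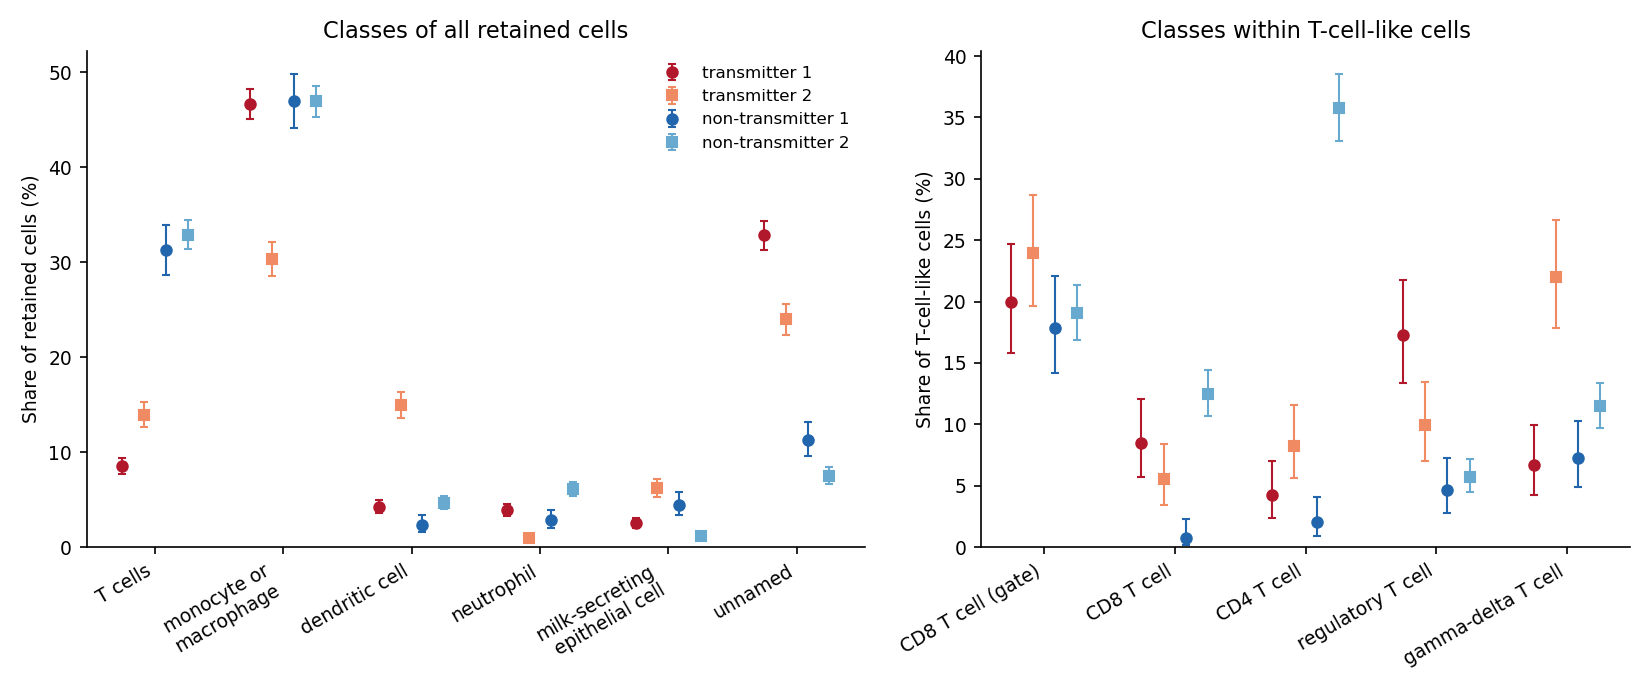
Share of each cell class per library in percent, of retained cells or of T cells as the axes state, with exact Clopper-Pearson 95% intervals. T cells took 8.5% and 13.9% of the transmitter libraries and 31.3% and 32.9% of the non-transmitter libraries.

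The series title puts CD8 T cells at the centre, so their expression was compared first. For expression and markers the gate was applied to all retained cells, giving 66, 92, 72 and 236 cells, of which 66, 87, 69 and 233 lie in T cell clusters. By cluster, FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230), an immediate early transcription factor, fell by 2.88 log2 units (SE 0.585) in the transmitter group. In CPM, UMIs scaled to a common library size, its levels were 35.6 and 37.3 against 439.0 and 254.7 (n = 2 each, adjusted p = 0.0159, edgeR quasi-likelihood with Benjamini-Hochberg). IFI6 (ENSG00000126709, chromosome 1, 27666061 to 27672218), an interferon-induced inhibitor of cell death, fell by 2.62 (SE 0.571, adjusted p = 0.0357), with 59.4 and 31.1 against 87.8 and 327.8 CPM. AC105402.3 (ENSG00000231079), an antisense transcript, rose to 463.0 and 571.6 CPM against 0 and 2.15 (170 against 2 UMIs, a ratio of 243 with a counting interval of 66.3 to 2020, adjusted p = 1.12e-07). MT-ND3, a mitochondrially encoded part of respiratory complex I, rose by 1.80 (SE 0.348, adjusted p = 0.0104). MTRNR2L12 (ENSG00000269028, chromosome 3, 96617188 to 96618236) rose by 2.54 (SE 0.569, adjusted p = 0.0421), and its sequence is nearly that of the mitochondrial MT-RNR2, so its source is uncertain. Non-transmitter 1 had 11393 UMIs in its 3 cells, so IFI6 and MTRNR2L12 each rest on 1 UMI there and AC105402.3 on 0.

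These 3 rises and 2 falls came from 3539 tested genes, of which 115 had an unadjusted p under 0.05; DESeq2 called 1. In 34.9% of tested genes the groups did not overlap, which chance gives in 2 of 6 labelings. AC105402.3 and MT-ND3 lie outside the naming rule and were chosen after their values were seen. The count was 18 without transmitter 1, 15 without non-transmitter 1, 13 without non-transmitter 2 and 1 with the gate. Without non-transmitter 2, FOS and IFI6 no longer passed, nor did MTRNR2L12, and AC105402.3 had an adjusted p of 0.0574. Without transmitter 1 or without transmitter 2, FOS, IFI6, MTRNR2L12 and MT-ND3 did not pass (highest adjusted p over the alternatives 0.9997 for each). Over the alternatives IFI6 passed in 3 of 12, and its log2 difference was -0.53 without non-transmitter 2, where that of MT-ND3 was 2.80. GNLY, a pore-forming granule protein, had a low p but did not pass, at log2 4.20 (adjusted p = 0.316).

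Tissue residence genes, which mark T cells that stay in tissue, had a median log2 difference of 0.39 in CD8 T cells by cluster, 9 of 13 being higher in the transmitter group (camera adjusted p = 0.159; 0 called, 0 adjusted over the list alone). That median was 0.17 without transmitter 1 and 1.16 without non-transmitter 2. By gate the median was -0.11 with 6 of 18 higher (adjusted p = 0.553), and it turned to 0.17 without transmitter 2. Recirculation genes, which let T cells leave tissue, had medians of 0.12 by cluster (adjusted p = 0.643) and 0.28 by gate (adjusted p = 0.298). Cytotoxic effector genes had a median of -0.11 and a mean of 0.17 by cluster, opposite in sign (adjusted p = 0.944, 0 called, 1 adjusted over the list alone, GNLY). By gate their median was -0.16 (adjusted p = 0.743). Homing receptors had medians of 0.38 by cluster (adjusted p = 0.545) and -0.01 by gate (adjusted p = 0.743), where the test pointed up.

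Interferon-stimulated genes, the antiviral response, were lower in the transmitter group for 19 of 19 measured genes by cluster (median -0.66, camera adjusted p = 3.53e-06; 1 called, 2 adjusted over the list alone). The adjusted p was 0.576 with an estimated correlation. By gate 27 of 28 were lower (median -0.66, adjusted p = 9.91e-09, and adjusted p = 0.791 with an estimated correlation). Without non-transmitter 2 the medians turned to 5.53 by cluster and 0.37 by gate, the former against the 3 cells of non-transmitter 1. Without non-transmitter 1 they were -1.19 and -1.46. By gate, MX1, which blocks viral replication, stood at 42.1 and 34.8 against 60.1 and 243.5 CPM. Immediate early and heat shock genes, which respond to stress and handling, were lower for 17 of 18 by gate (median -0.45, adjusted p = 1.34e-08, and adjusted p = 0.675 with an estimated correlation). In gated cells the median was -0.12 without non-transmitter 1, where the call ended (adjusted p = 0.0820), and -0.93 without non-transmitter 2. By cluster 10 of 13 were lower (median -0.48, adjusted p = 3.53e-06; adjusted p = 0.393 with an estimated correlation), and the call ended without transmitter 2 (median -0.21, adjusted p = 0.179). JUNB, a partner of FOS, had 346.7 and 272.5 against 1045 and 801.2 CPM by gate, log2 -1.56.

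Activation and checkpoint genes were lower for 8 of 9 by cluster (median -0.46, adjusted p = 8.5e-05; adjusted p = 0.473 with an estimated correlation) and 10 of 16 by gate (adjusted p = 0.553). Class I antigen processing genes were lower for 12 of 12 by cluster (median -0.56, adjusted p = 0.00970; adjusted p = 0.769 with an estimated correlation). Class II presentation genes were lower for 5 of 6 (median -0.62, adjusted p = 0.00404; adjusted p = 0.393 with an estimated correlation). Inflammatory cytokines and chemokines were lower for 5 of 6 (median -1.06, adjusted p = 1.75e-05; adjusted p = 0.393 with an estimated correlation). By gate class I genes did not pass (median -0.42, adjusted p = 0.0823), while class II genes (7 of 7 lower, median -0.46, adjusted p = 0.0319) and inflammatory genes (9 of 10 lower, median -0.89, adjusted p = 0.000119) did. With an estimated correlation the adjusted p of these 2 were 0.791 and 0.674. By gate the class II call ended without transmitter 1 (median -0.29) and without non-transmitter 2 (median -0.12), and the inflammatory median was -1.73 and -1.35 without the same libraries. Without transmitter 2 none of these 4 lists passed in the CD8 T cell clusters, with medians of -0.16, -0.18, -0.37 and -0.26 (adjusted p = 0.380, 0.926, 0.128 and 0.380). Without transmitter 1 class I genes (adjusted p = 0.289) and class II genes (adjusted p = 0.0612) did not pass, activation genes stood at -0.92 and inflammatory genes at -1.91. Without non-transmitter 2 class I genes turned to 1.95, activation genes stood at -0.9965 and class II genes at -1.02, and without non-transmitter 1 the latter stood at -0.29. Lipid handling genes of macrophages, markers of another cell type, were lower for 12 of 15 in gated cells (median -1.02, adjusted p = 6.7e-07; adjusted p = 0.674 with an estimated correlation). That median was -1.54 without transmitter 2 and -0.66 without non-transmitter 2. Among these genes the secreted protein SPP1 had 14.9 and 29.9 against 208.1 and 84.7 CPM. Oxidative phosphorylation genes had medians of 0.16 by cluster (adjusted p = 0.944) and 0.01 by gate (adjusted p = 0.553). Proliferation genes were measured in the gate (median -0.28, adjusted p = 0.402), as were milk epithelium genes (median 0.05, adjusted p = 0.402) and neutrophil genes (median -0.43, adjusted p = 0.474). With an estimated correlation, 0 lists were called in any of the 9 classes and their settings (lowest adjusted p = 0.190), against 6 of 12 by cluster and 5 of 15 by gate with the preset value.

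Residence at the level of single cells was read as the share of CD8 T cells with a UMI of each marker, after thinning every cell to 2000 UMIs. By gate, CD69 (ENSG00000110848, chromosome 12, 9752486 to 9760901), which holds T cells in tissue, was found in 58.7% and 64.8% of transmitter cells and 66.7% and 80.0% of non-transmitter cells. The means were 61.8% ± 4.32 and 73.3% ± 9.43 (n = 2 each, exact permutation p = 0.333). ITGAE (ENSG00000083457, chromosome 17, 3714628 to 3801243), the CD103 integrin that binds epithelium, was found in 13.9% ± 7.25 and 16.0% ± 3.27 (exact permutation p = 1). CXCR6, a homing receptor, was found in 9.71% against 6.95%, the integrin ITGA1 in 11.3% against 11.7%, and the regulator ZNF683 in 4.88% against 6.39% (exact permutation p = 1 each). The exit receptor S1PR1 was found in 2.69% against 4.02%, its regulator KLF2 in 39.7% against 40.8%, and the chemokine receptor CCR7 in 5.37% against 4.24% (exact permutation p = 1 each). These shares rest on 154 and 296 cells, with 3, 1, 6 and 6 cells left out for too few UMIs, and median depths before thinning of 5968, 8510.5, 5456 and 6678.5.

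In milk-secreting epithelial cells, which should lack T cell markers, thinned CD69 was found in 0 of 89, 149, 36 and 42 cells. Read as at most 3 counts, these zeros allow shares of up to 3.37%, 2.01%, 8.33% and 7.14%. The upper Clopper-Pearson bounds in the figure are somewhat higher. ITGAE was found in 6.61% ± 2.99 and 7.14% ± 10.1 of these cells, which had median depths of 13553, 13462, 3711 and 5411 UMIs before thinning. Without thinning, CD69 reached 86.8% and 92.5% of gated CD8 cells (exact permutation p = 0.667) against 2.27% and 4.32% of epithelial cells. Unthinned ITGAE reached 31.3% and 33.2% of gated cells and 37.3% and 15.5% of epithelial cells, which were deeper than gated cells in the transmitter group.

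By cluster, thinned shares for the transmitter and non-transmitter groups rest on 45 and 151 cells, with 3 of the latter in non-transmitter 1. CD69 was found in 48.0% ± 11.3 against 52.8% ± 27.5 and ITGAE in 22.0% against 24.8% (exact permutation p = 1 each). ITGA1 was found in 20% against 6.76% (exact permutation p = 0.333), CXCR6 in 19.0% against 5.07% (p = 0.667) and KLF2 in 45.0% against 64.8% (p = 0.333). The ITGA1 difference of 13.2 points was 6.49 without non-transmitter 1 and 20 without non-transmitter 2. The CXCR6 difference of 13.9 points came from 28% and 10% against 0% and 10.1% of the libraries, and it was 4.93 without transmitter 1 and 8.86 without non-transmitter 1. The CD69 difference turned to 3.18 points without transmitter 2 and 14.7 without non-transmitter 2, and that of ITGAE to 5.78 without non-transmitter 1. ZNF683 was found in 7.5% against 1.35%, a difference of -1.35 points without transmitter 2. S1PR1 was found in 6.5% against 4.39%, a difference of -2.28 without non-transmitter 1. CCR7 was found in 2.5% against 3.72%, turning to 1.28 without transmitter 1 and 2.5 without non-transmitter 2. Left out for depth were 3, 0, 0 and 4 cells.

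**Figure D2:**
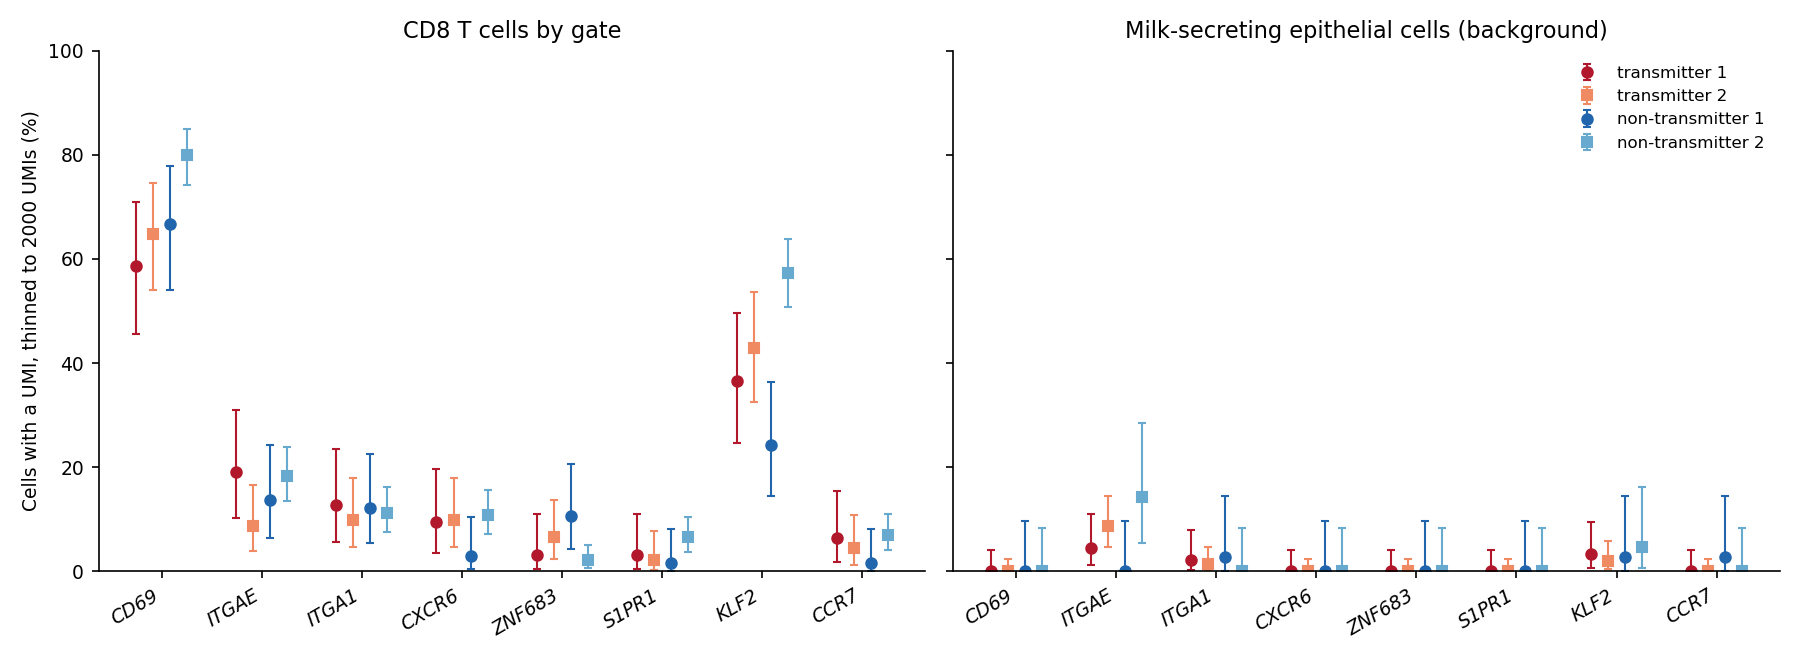
Share of gated CD8 T cells, and of milk-secreting epithelial cells as background, with a UMI of each residence or recirculation marker after thinning to 2000 UMIs, in percent per library with exact Clopper-Pearson 95% intervals. In gated cells CD69 ranged from 58.7% to 80.0% and ITGAE stayed far below it in all 4 libraries.

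The same comparison was made in every class with at least 20 cells in each library. In all T cells together, interferon-stimulated genes were lower for 35 of 35 (median -1.17, camera adjusted p = 1.84e-16; adjusted p = 0.472 with an estimated correlation; 0 called, 0 adjusted over the list alone). The mean log2 level of the list was 5.01, 5.01, 5.16 and 6.71, so non-transmitter 2 stood apart, and without it the median was 0.03; without non-transmitter 1 it was -1.78. Gamma-delta T cells had 24 of 26 lower (median -0.68, adjusted p = 1.02e-05; adjusted p = 0.613 with an estimated correlation), with medians of 1.56 without non-transmitter 2 and -1.60 without non-transmitter 1. Immediate early genes were lower for 20 of 21 in T cells (median -0.62, adjusted p = 3.37e-12; adjusted p = 0.472 with an estimated correlation) and for 15 of 15 in gamma-delta T cells (median -1.24, adjusted p = 4.11e-12; adjusted p = 0.613 with an estimated correlation). In T cells that median was -0.05 without non-transmitter 1, and the call ended (adjusted p = 0.152), and it was -0.9971 without non-transmitter 2. In gamma-delta T cells it was -0.46 and -1.97 without the same libraries. Milk epithelium genes, of another cell type, had mean log2 levels of 6.06, 5.48, 5.68 and 2.98 in gamma-delta T cells (3 measured), lowest in non-transmitter 2. FOS stood at 77.6 and 68.4 against 598.9 and 513.2 CPM in T cells (log2 -2.95, SE 0.299, adjusted p = 0.126). In T cells, genes of other cell types moved with the groups: milk epithelium genes (median 1.25, adjusted p = 0.0009), lipid handling genes (median -0.80, adjusted p = 5.03e-05) and neutrophil genes (median -0.98, adjusted p = 5.03e-05). With an estimated correlation their adjusted p were 0.588, 0.472 and 0.472. Without non-transmitter 2 the milk list stood at 0.02 and the neutrophil list at -0.00086, both no longer called (adjusted p = 0.852 each). Without non-transmitter 1 the lipid list was not called (median -0.26, adjusted p = 0.586), the milk list stood at 2.32 and the neutrophil list at -1.79. Without transmitter 1 the neutrophil list stood at -1.98. In T cells without myeloid-led subclusters, neither the lipid list (median -0.21, adjusted p = 0.640) nor the neutrophil list (median -0.58, adjusted p = 0.163) was called.

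Macrophages had 35 of 35 interferon-stimulated genes lower in the transmitter group (median -1.29, adjusted p = 1.22e-42; adjusted p = 0.413 with an estimated correlation; 0 called, 30 adjusted over the list alone). RSAD2, an antiviral enzyme, had 10.5 and 12.3 against 47.7 and 46.1 CPM, and IFITM3, which blocks virus entry, had 35.4 and 58.8 against 189.1 and 369.1. The median was -0.92 without non-transmitter 2, where non-transmitter 1 alone stood for its group. Macrophages had median depths of 24006, 18263, 939 and 17680 UMIs, and the libraries drew on different macrophage clusters. The difference in this list cannot be told apart from that mix, though the median was -1.305 without shallow macrophage clusters. Immediate early and heat shock genes were lower for 19 of 21 in macrophages (median -0.54, adjusted p = 2.81e-09; adjusted p = 0.308 with an estimated correlation), with a median of -0.25 without non-transmitter 2. Lipid handling genes were higher for 13 of 21 (median 0.28, adjusted p = 0.0423; adjusted p = 0.496 with an estimated correlation), a call lost without transmitter 1 (median 0.08, adjusted p = 0.333) and without non-transmitter 2 (median 0.32, adjusted p = 0.209). It was lost as well without shallow macrophage clusters (median 0.14, adjusted p = 0.101), and without non-transmitter 1 the median was 0.15. The fatty-acid carrier FABP4 stood at 1744 and 2167 against 692.4 and 102.6 CPM. The anticoagulant TFPI had 90.6 and 71.1 against 9.24 and 6.84 CPM (log2 3.32, SE 0.303, adjusted p = 0.129). FABP4 and TFPI were both among the lead genes of the macrophage cluster that held 320, 441, 24 and 7 cells. Their differences in the whole class therefore cannot be told apart from this mix of clusters. In dendritic cells 34 of 34 interferon-stimulated genes were lower (median -1.69, adjusted p = 2.28e-16; adjusted p = 0.624 with an estimated correlation), and the median was -0.01 without non-transmitter 2. Their proliferation genes were lower for 13 of 14 (median -1.02, adjusted p = 6.93e-10, and adjusted p = 0.306 with an estimated correlation). Among them MKI67 stood at log2 -4.88, from 4 against 36 UMIs, and did not pass (adjusted p = 0.555, edgeR quasi-likelihood). Dendritic cells joined a cluster led by CD1C and FCER1A (111, 260, 12 and 161 cells) with another led by CCL22 and LAMP3 (53, 129, 17 and 11). Differences in this class cannot be told apart from that mix.

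In neutrophils 29 of 29 interferon-stimulated genes were lower (median -1.53, camera adjusted p = 1.92e-15; adjusted p = 0.427 with an estimated correlation; 6 called, 15 adjusted over the list alone). IFIT2, which binds viral RNA, fell by 3.31 (SE 0.496, adjusted p = 0.000131), from 2079 and 1752 CPM in the non-transmitter group to 216.7 and 182.0. IFI6 fell by 3.53 (adjusted p = 0.000155) and EPSTI1, another interferon-induced gene, fell by 4.09 (adjusted p = 0.00282). HERC6, an interferon-induced ligase, had a ratio of 0.0225 (counting interval 0.000559 to 0.131, adjusted p = 0.00989), and RPS20, a ribosomal protein, fell by 3.48 (adjusted p = 0.0283). CFD, complement factor D, rose by 4.42 (adjusted p = 0.00255), at 234.8 and 424.6 against 0 and 13.9 CPM. Without transmitter 1 CFD and EPSTI1 did not pass, nor did CFD without non-transmitter 2, RPS20 without transmitter 2, HERC6 and RPS20 with DESeq2, or any of these 6 genes without a low-count filter. The log2 difference of CFD was 7.90 without non-transmitter 2, that of EPSTI1 -8.16 without transmitter 1 and that of HERC6 -7.77 without transmitter 2. Immediate early and heat shock genes were lower for 8 of 11 in this neutrophil class (median -0.86, adjusted p = 0.0215; adjusted p = 0.467 with an estimated correlation). They were not called without transmitter 1 (median -1.03, adjusted p = 0.0612) or without non-transmitter 1 (median -0.40, adjusted p = 0.774), and the median was -1.53 without non-transmitter 2. Neutrophils had 151, 25, 35 and 226 cells at median depths of 1105, 1244, 811 and 1196.5 UMIs. They formed a single cluster, and IFIT2, IFIT3 and IFITM2 were among its lead genes. The unnamed clusters closest to neutrophils were not tested, so these results hold for the named cluster only. Lipid handling genes, markers of macrophages, had mean log2 levels of 6.65, 7.17, 7.21 and 8.31 in it, with the transmitter libraries lowest. All adjusted p for single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

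**Figure D3:**
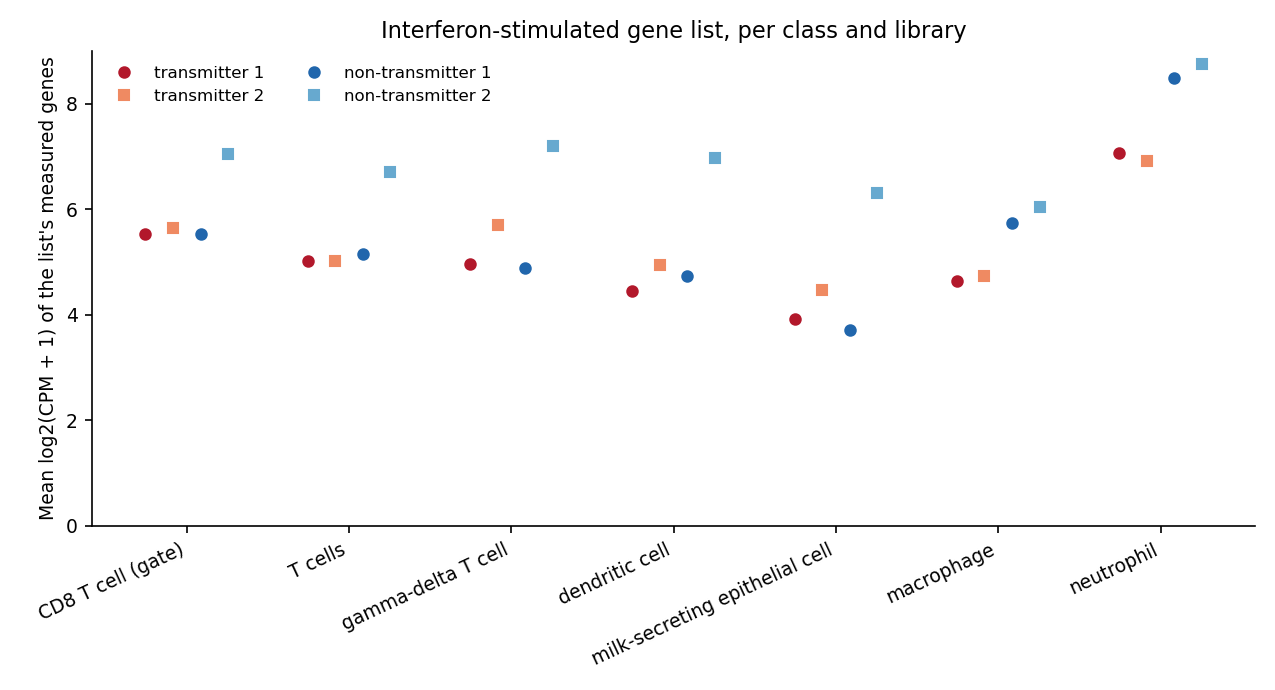
Mean log2 level, log2(CPM + 1), of the measured interferon-stimulated genes per class and library. In macrophages and neutrophils both non-transmitter libraries lie above both transmitter libraries, while in T cells and dendritic cells the difference comes from non-transmitter 2.

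In milk-secreting epithelial cells 22 of 25 interferon-stimulated genes were lower (median -1.62, adjusted p = 1.36e-08; adjusted p = 0.531 with an estimated correlation), and the median was -0.14 without non-transmitter 2, where the call ended (adjusted p = 0.192), and -2.60 without non-transmitter 1. Of the epithelial cells of non-transmitter 2, 39 of 44 sat in the cluster led by LALBA. Macrophage lipid genes in the same cells were lower for 18 of 19 (median -2.24, adjusted p = 2.6e-15; adjusted p = 0.409 with an estimated correlation), and at -1.26 without non-transmitter 2. In all cells summed, which also carries class composition, 35 of 35 interferon-stimulated genes were lower (median -1.77, adjusted p = 4.28e-32; adjusted p = 0.524 with an estimated correlation). Without non-transmitter 2 that median was -0.65. The T cell receptor chain TRAC had a log2 difference of -2.68 (adjusted p = 0.9998). Erythrocyte and platelet genes were measured only in all cells (3 of the list, median 0.54, adjusted p = 0.544).

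Beyond these genes, AC105402.3 was the one transcript called in most classes. It spans chromosome 2 from 148866470 to 148888823 on the minus strand, opposite KIF5C (148875250 to 149026759, plus strand) and across a pair of processed pseudogenes, so its reads cannot be assigned with certainty. In gated CD8 cells it rose by 7.30 log2 units (adjusted p = 0.000967) and in T cells by 7.38 (SE 0.458, 613.7 and 861.0 against 6.06 and 3.47 CPM, adjusted p = 0.00894). In macrophages it had 501.9 and 685.3 against 0 and 0.0552 CPM, a ratio of 12100 (counting interval 2180 to 480000, adjusted p = 0.00323). In dendritic cells it was at least 716-fold higher and in neutrophils at least 125-fold higher, against a floor of 3 counts over the group (adjusted p = 0.0442 and 1.18e-07). In all cells it rose by 9.31 (adjusted p = 0.019) and did not pass without non-transmitter 2.

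**Figure D4:**
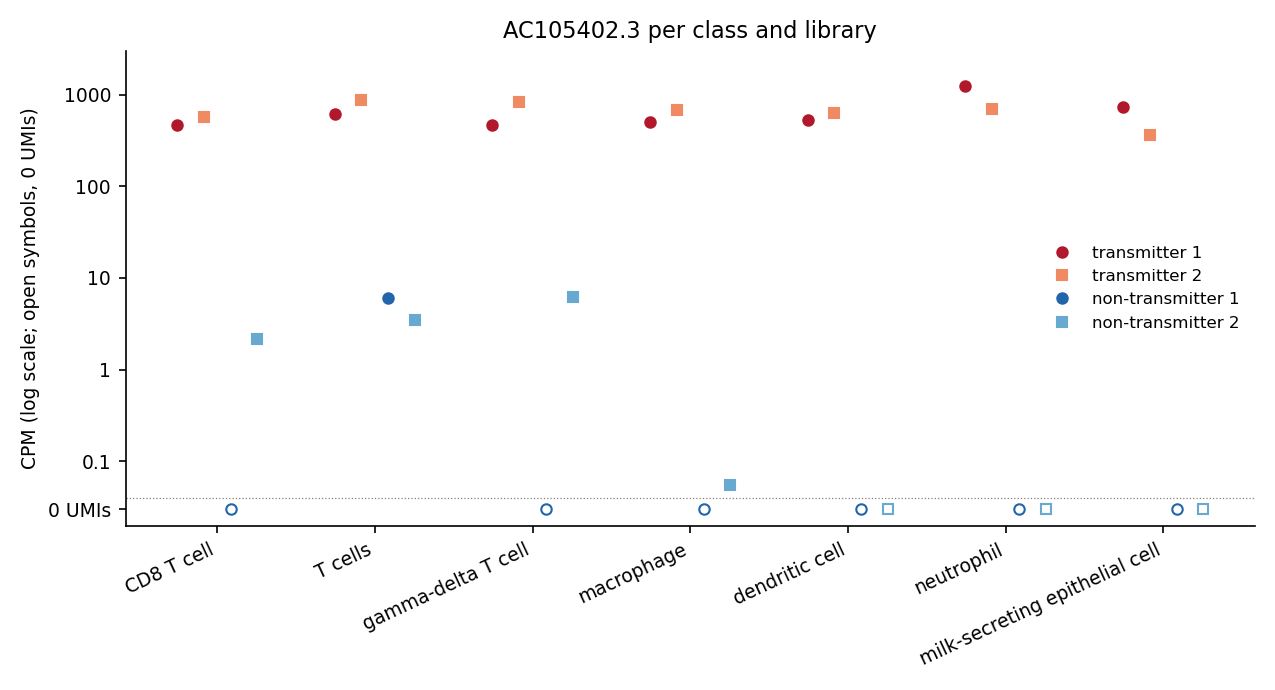
AC105402.3 in CPM on a log scale, per class and library, with open symbols for 0 UMIs. The transmitter libraries lie between 364.0 and 1237 and the non-transmitter libraries at or below 6.20.

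The number of genes past adjusted p 0.05 by edgeR was 1 of 7796 in gated CD8 cells (186 at an unadjusted p under 0.05; DESeq2 11), 1 of 11948 in T cells (349; DESeq2 11), 1 of 15768 in macrophages (1048; DESeq2 102) and 1 of 11842 in dendritic cells (554; DESeq2 25). It was 0 of 6257 in gamma-delta T cells (90; DESeq2 2), 0 of 9936 in epithelial cells (679; DESeq2 66), 21 of 1992 in neutrophils (292; DESeq2 11) and 1 of 20712 in all cells (920; DESeq2 110). Single libraries moved these counts. Without non-transmitter 1 they were 42 in gated CD8 cells, 537 in T cells, 14 in gamma-delta T cells, 57 in macrophages, 85 in dendritic cells, 49 in neutrophils, 985 in epithelial cells and 23 in all cells. Without non-transmitter 2 they were 244 in gated CD8 cells, 94 in T cells, 296 in gamma-delta T cells, 13 in dendritic cells, 33 in epithelial cells and 0 in all cells. Without transmitter 1 they were 14 in gated CD8 cells, 8 in T cells, 2 in gamma-delta T cells, 3 in macrophages, 10 in dendritic cells and 10 in neutrophils. Without transmitter 2 they were 6 in gated CD8 cells, 7 in T cells, 3 in gamma-delta T cells and 10 in dendritic cells.

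Viral transcripts could not be compared. The 187 features without a human gene identifier, 173 of them named for human herpesvirus, had 0 UMIs in all 4 libraries. A count of 0 allows up to 0.0665, 0.0788, 0.444 and 0.0648 CPM.

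Barcodes with over 20% of UMIs from mitochondrially encoded genes, a sign of damaged or dying cells, were removed before the main comparisons above. They made up 7.27% (Clopper-Pearson 95% interval 6.52 to 8.09) and 14.8% (13.5 to 16.1) of the transmitter libraries, and 3.57% (2.63 to 4.74) and 1.5% (1.14 to 1.94) of the non-transmitter libraries. The means were 11.01% ± 5.29 and 2.54% ± 1.47 (n = 2 each, exact permutation p = 0.333). Macrophages held most of them: 33.6% and 36.4% of barcodes assigned to macrophages were over the limit in the transmitter libraries, against 6.62% and 4.26%. Among barcodes assigned to T cells the shares were 5.32% and 7.42% against 1.02% and 0.648%.

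**Figure D5:**
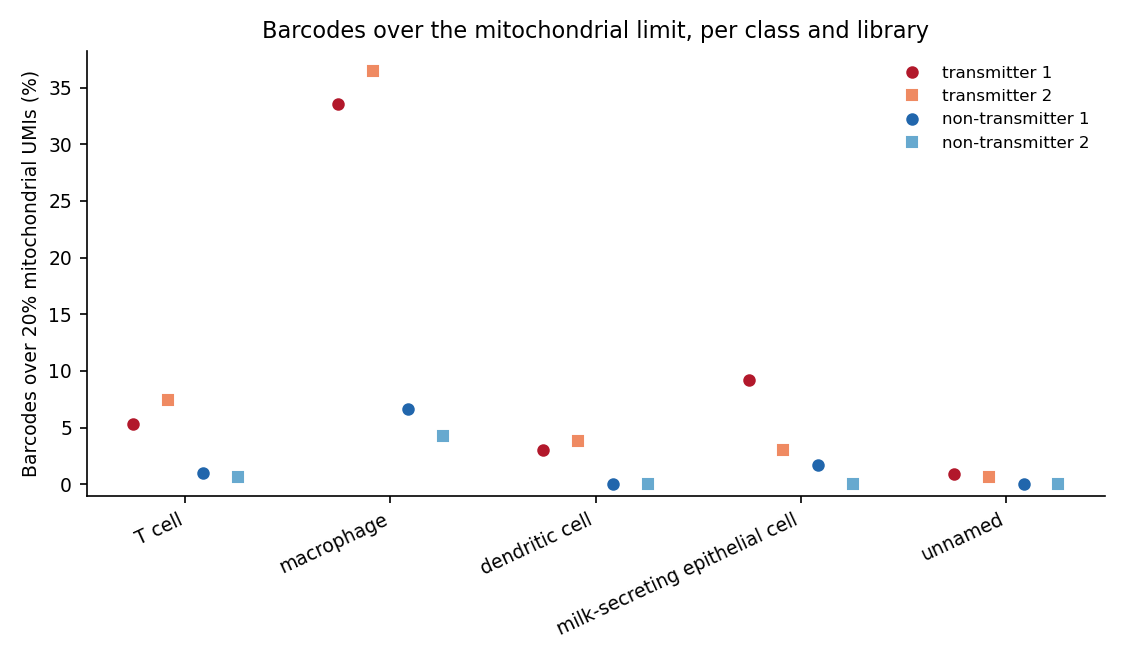
Share of barcodes over 20% mitochondrial UMIs, in percent, per assigned class and library. In macrophages the transmitter libraries reached 33.6% and 36.4% and the non-transmitter libraries 6.62% and 4.26%.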

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

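The 3 tests of the interferon list were chosen only after the result was seen, while the test of class composition was set before it.

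Signal appeared in barcodes left out of the main comparisons: 7.274% of barcodes in transmitter 1 and 14.75% in transmitter 2 were over the mitochondrial limit. A shift in cell classes was tested, since macrophages held most of these barcodes. In share over the limit, both transmitter libraries exceeded both non-transmitter libraries in 5 of 5 classes with enough barcodes. This argues against a shift between these classes as the whole cause. The unnamed cells counted as a class, and dendritic cells had only 5, 15, 0 and 0 barcodes over the limit. Clusters within a class were not compared. The macrophage cluster led by FABP4 (320, 441, 24 and 7 cells) had a median mitochondrial share of 4.82%, and that led by HS3ST2 (63, 172, 60 and 870) 2.66%. A shift within classes thus stays open. Damage to cells before or during handling may differ between the groups, but the labels give no handling record, so this and a biological difference stay open and untested.

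Effects of the group differed between T cells and monocytes or macrophages for 8 gene lists, by an interaction term tested with camera at the preset correlation. With an estimated correlation, none of the 8 passed. Positive values mean that T cells differed less downward or more upward in the transmitter group than the myeloid cells did. The median difference of log2 fold changes was 0.7851 for cytotoxic effector genes (adjusted p = 8.86e-07, and adjusted p = 0.383 with an estimated correlation) and 0.7635 for proliferation genes (adjusted p = 0.000221, and 0.586). It was -1.013 for inflammatory cytokines and chemokines (adjusted p = 1.34e-07, and 0.12) and -0.8158 for lipid handling genes (adjusted p = 8.84e-06, and 0.533). The mix of monocytes and macrophages differed between libraries, and the inflammatory list stood at 0.39 in both together but at -0.55 in macrophages alone, the direction of T cells. Oxidative phosphorylation genes had -0.2464 (adjusted p = 0.0165, and 0.533). Markers of other cell types had 1.817 for milk-secreting epithelium and -1.689 for neutrophils (adjusted p = 3.1e-12 each, and 0.12 each), and the neutrophil list stood at 0.12 in both together but at -0.36 in macrophages alone. No single gene passed the interaction test by edgeR quasi-likelihood with Benjamini-Hochberg adjustment: 0 of 15943, with 501 at an unadjusted p under 0.05, and no other tool was run on it.

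Interferon-stimulated genes had an interaction of 0.7148 (adjusted p = 1.99e-17, and adjusted p = 0.12 with an estimated correlation), their difference being smaller in T cells than in monocytes and macrophages together. In macrophages alone the median was -1.29, close to the -1.17 of T cells. The pool includes the monocyte cluster led by CXCL10 and CCL8, with 16, 8, 4 and 543 cells. A single library was weighed first: without non-transmitter 2 the lowest median over T cells, gated CD8 T cells and dendritic cells was -0.01336, so in these classes that library alone may carry the difference. In macrophages and the named neutrophil cluster the median nearest to 0 without it was -0.9186, which argues against 1 library as the whole cause there. Macrophages of the non-transmitter group then came from non-transmitter 1 alone, at a median of 939 UMIs against 24006 and 18263 in the transmitter libraries. Of these 569 cells, 422 sat in the shallow cluster led by APOE and CTSD. Depth and cluster mix thus cannot be told apart from the group in macrophages. Free monocyte RNA in the T cells of that library would bring the abundant chemokines CCL2, CCL7, CCL8 and CXCL10 along, but the interferon list stood 76.3 times higher relative to them in T cells than in all cells, which argues against it. A stronger interferon response in the non-transmitter milk stays a hypothesis, and donors or handling that differ along with the groups were not tested.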

How the results depend on the processing

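Alternatives chosen after seeing the data were the removal of top doublet scores, macrophages without shallow clusters, pooled monocytes and macrophages, T cells without myeloid-led subclusters for genes, lists and shares, all barcodes and stricter filters for gene counts outside the planned ones, and doublets kept for all cells. Of 377 alternatives to the 34 results that answer a comparison, 264 kept direction and side of the threshold, 39 lost the threshold or a count, 47 gained and 27 reversed. For 131 named genes and single lists, 1272 of 1652 kept both, 160 were weaker, 199 stronger and 21 reversed. Except where fewer genes or libraries entered by construction, the cause was not tested. Shares could not pass the permutation test in any setting, so their stability is in direction only. In simulated data of the same size, 8-fold changes were recovered for 80.3% of genes in CD8 T cells, 93.9% in T cells and 100% in macrophages, 4-fold changes for 35.8%, 46.3% and 88.1%, and 2-fold changes for 2.99%, 4.48% and 5.97%. By gate these were 78.8%, 56.7% and 1.49%, and in neutrophils 92.4%, 50.7% and 4.48%. False calls were 1 of 80 in CD8 T cells, 10 of 101 by gate, 10 of 106 in T cells, 16 of 145 in macrophages and 5 of 103 in neutrophils, so by gate, in T cells and in macrophages more than the 5% set. No simulation varied depth or the number of libraries. Each held 200 changed genes, all with a mean log2 CPM of at least 4, so recovery among less expressed genes was not measured. Many calls also ease the Benjamini-Hochberg threshold. The tests of T cells and macrophages called 1 gene each, so recovery in the data may be lower. There FOS in T cells (log2 -2.95, SE 0.299) and TFPI in macrophages (log2 3.32, SE 0.303) did not pass.

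Differences in share, in points, reversed under stricter filters to -2.03 for CD8 T cells, -3.38 for gated CD8 T cells, -3.83 for gamma-delta T cells and 4.14 for other T cells. At Leiden resolution 2.0 they reversed to -1.35 for CD8 T cells, -3.89 for gamma-delta T cells, 3.76 for other T cells and 7.08 for monocytes and macrophages together. Other T cells reversed to 0.251 with all barcodes, and monocytes to -0.818 with doublets kept. Without myeloid-led subclusters they reversed to -0.492 for CD8 T cells, -1.02 for gated CD8 T cells and 6.29 for other T cells, and T cells stood at -13.7. Neutrophils stood at -5.41 with doublets kept, and CD8 T cells at 8.23 at Leiden resolution 0.5. With libraries centred they reversed to 1.77 for CD4 T cells, 0.819 for monocytes and macrophages and -5.5 for dendritic cells. Residence markers reversed without thinning to 6.89 for ITGAE and 0.764 for KLF2. At 4000 UMIs they reversed to 1.43 for CD69, 4.97 for KLF2 and 2.51 for CCR7. With the gate they reversed to -0.419 for ITGA1, -1.51 for ZNF683, -1.33 for S1PR1 and 1.14 for CCR7.

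Genes called in CD8 T cells numbered 3 with DESeq2 size factors in edgeR, 1 with DESeq2, 35 with at least 10 counts, 16 with equal cell numbers, 3 with doublets kept, 1 with stricter filters, 14 with all barcodes and 1 with the gate, against 5. By gate the count was 11 with DESeq2 and 18 without a low-count filter, against 1. With DESeq2 the other classes had 11 in T cells, 2 in gamma-delta T cells, 102 in macrophages, 25 in dendritic cells, 11 in neutrophils, 66 in epithelial cells and 110 in all cells. Without a low-count filter they had 33, 4, 302, 100, 1 and 298, all cells being within 1.5 times. With at least 10 counts gamma-delta T cells and epithelial cells had 1 each, and with stricter filters gamma-delta T cells had 1. Neutrophils had 48 with doublets kept and 44 with all barcodes. Neutrophils formed no cluster under stricter filters or at Leiden resolution 0.5, so no value exists there.

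With a block by replicate number, T cells had 10 genes called, gamma-delta T cells 1, macrophages 6, dendritic cells 3, neutrophils 0 and all cells 0. The libraries share only a number, and deviations of equally numbered libraries correlated at r = -0.167 over 7516 genes, which gives no ground for pairing.

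Gene lists called with an estimated correlation were 0 in CD8 T cells by cluster and by gate, T cells, gamma-delta T cells, macrophages, dendritic cells, neutrophils, epithelial cells and all cells. With fry's directional test they were 0 in these classes except 1 in dendritic cells (proliferation, adjusted p = 0.0332) and 1 in all cells (cytotoxic effector, adjusted p = 0.0214). T cells without myeloid-led subclusters had 5 against 8, where the lipid list at -0.21 and the neutrophil list at -0.58 were no longer called and the interferon list stood at -1.18, and macrophages without shallow clusters had 7 against 11.

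Leaving out 1 library at a time, share differences ranged from -5.44 to 6.22 for CD8 T cells, -29.5 to 4.18 for CD4 T cells, -2.69 to 12.7 for gamma-delta T cells, -26.4 to 24.2 for other T cells, -0.414 to 0.0897 for B cells, -6.27 to 24.9 for monocytes, 0.74 to 11.4 for dendritic cells, -3.65 to -0.41 for neutrophils and -0.319 to 3.35 for epithelial cells. Marker differences ranged from -24.3 to 14.7 for CD69, 6.49 to 20 for ITGA1, 4.93 to 22.9 for CXCR6, -11.3 to 5.78 for ITGAE, -1.35 to 13.6 for ZNF683, -2.28 to 6.5 for S1PR1 and -4.93 to 2.5 for CCR7. Gene counts ranged from 5 to 18 in CD8 T cells, 6 to 244 by gate, 7 to 537 in T cells, 2 to 296 in gamma-delta T cells, 1 to 57 in macrophages, 10 to 85 in dendritic cells, 10 to 49 in neutrophils, 0 to 985 in epithelial cells and 0 to 23 in all cells. Lists called ranged from 2 to 7 in CD8 T cells, 5 to 8 by gate, 5 to 10 in T cells, 3 to 8 in gamma-delta T cells, 5 to 13 in macrophages, 4 to 8 in dendritic cells, 2 to 5 in neutrophils and 4 to 10 in epithelial cells. Interferon medians ranged from -1.188 to 5.526 in CD8 T cells, -1.462 to 0.3725 by gate, -1.78 to 0.02624 in T cells and -1.597 to 1.561 in gamma-delta T cells. The residence median by gate ranged from -0.4659 to 0.1731. Where a group was left with 1 library, it was assumed to vary like the other group.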

Other observations

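Among the tests of AC105402.3, those by depth and by mitochondrial share were set before the result was seen, and those of milk transcripts, of 1 cell class and of 1 fixed mitochondrial rate after it.

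In dendritic cells, lipid handling genes, which take up and carry fats, were compared between the groups. For this list 14 of 21 genes were higher (median 0.57, camera adjusted p = 0.00457, and adjusted p = 0.624 with an estimated correlation; 0 called, 3 adjusted over the list alone). In dendritic cells the call ended without transmitter 2 (median -0.16), without non-transmitter 1 (0.39) and without non-transmitter 2 (0.92, adjusted p = 0.0508), and without transmitter 1 the median was 1.04. FABP4, a fatty-acid carrier, stood at 27.9 and 147.2 against 0 and 1.24 CPM (log2 6.31, adjusted p = 0.785 by edgeR quasi-likelihood with Benjamini-Hochberg). Inflammatory cytokines and chemokines were higher for 14 of 19 in the same cells (median 0.58, adjusted p = 0.00496, and adjusted p = 0.624 with an estimated correlation). That call ended without transmitter 1 (median -0.22) and without non-transmitter 1 (0.41), and the median was 1.02 without transmitter 2 and 1.06 without non-transmitter 2. IL2RA, a receptor chain for interleukin 2, had a log2 difference of 5.58 that did not pass. The mix of dendritic cell clusters led by CD1C and by CCL22 differed between libraries, so these differences cannot be told apart from it. Neutrophil genes did not pass in these cells (8 of 14 higher, median 0.67, camera adjusted p = 0.0681). Milk epithelium genes, also of another cell type, had mean log2 levels of 3.76, 4.36, 3.54 and 2.96 in them (5 measured), with the transmitter libraries highest.

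In milk-secreting epithelial cells DEFB1, an antimicrobial peptide, stood at log2 4.07 and the mucosal chemokine CXCL17 at log2 3.47. KLK7, a protease, had a ratio of 46.8 (counting interval 8.34 to 1860). None of these passed (0 of 9936 by edgeR quasi-likelihood, 679 at an unadjusted p under 0.05, 66 by DESeq2). Without non-transmitter 1 the count was 985 and without non-transmitter 2 it was 33. DEFB1 was among the lead genes of the epithelial cluster that held 53, 103, 32 and 5 cells. Class II presentation genes, typical of white blood cells, were lower for 11 of 11 in these cells (median -2.47, adjusted p = 2.09e-08, and adjusted p = 0.531 with an estimated correlation), and at -0.68 without non-transmitter 2. The cluster named plasmacytoid dendritic cell, in which 6 listed markers of that class were detected, held 15, 187, 3 and 1 cells. JCHAIN, listed beforehand as a plasma cell marker, was among its lead genes.

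AC105402.3 was found in 87.0% and 83.7% of transmitter cells and 0.648% and 0.833% of non-transmitter cells. RNA set free by 1 cell class would leave the other classes far below that class. Among the tested classes the lowest had 0.3743 and 0.4228 of the level of the highest in the transmitter libraries. This argues against a tested class as the source. Unnamed clusters, 32.8% and 24.0% of these libraries, were not among them. The shallowest of 4 equal groups of barcodes stood at 2225 and 1380 CPM, above the 1237 and 861.0 of the highest tested class. An unnamed class as the source was thus not tested. Free RNA in general was tested by depth in 4 equal groups of barcodes: the deepest had 0.2338 and 0.3501 of the CPM of the shallowest, on both sides of a limit set beforehand, which left that test open. Outside epithelial cells, UMIs per barcode rose 9.605 and 14.96 times from the shallowest to the deepest group, against 3.82 and 2.52 times for CSN2, CSN3, CSN1S1 and LALBA, which reach these cells as free RNA. The rise was thus 2.515 and 5.935 times that of the milk transcripts (95% intervals 2.039 to 3.102 and 4.464 to 7.892), which argues against free RNA as the whole cause, while how much of the level it gives stays open. Reads shared with mitochondrial transcripts could raise it in barcodes rich in them, and the group highest in mitochondrial share had 2.945 times the level of the lowest in transmitter 2 but 0.9315 times in transmitter 1, so this cannot be told apart either. A fixed rate of sharing is argued against, since per mitochondrial UMI the non-transmitter libraries had at most 0.00538 of the transmitter level, while a sequence difference between donors or anything handled along with the groups stays untested.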
